A study of Mus musculus with 29 samples.

How the data were processed

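The study measured DNA copy number by array comparative genomic hybridisation in 29 medulloblastomas of mice with 1 functional copy of Ptch1. Each tumour was hybridised together with ear DNA of the same mouse on a 2-colour Agilent oligonucleotide array. By the labels, 19 tumours came from mice given 500 mGy at once on postnatal day 1 (acute), 9 from mice given 500 mGy spread over postnatal days 1 to 4 (protracted), and 1 from an unirradiated mouse (spontaneous). The mice were F1 animals of a C3H parent and a parent carrying the Ptch1 mutation. Tumours are named by group and by the number the labels give them. Each tumour is a separate mouse, and no test against the 1 spontaneous tumour was made.

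The arrays came in 2 designs. The larger set, 24 arrays, carried 52502 different probes, and the smaller set, 5 arrays, carried 53686, with 40539 probes in common. Per the file headers, the scans were quantified with Agilent Feature Extraction 10.5.1.1 for the 24 arrays and 10.7.3.1 for the 5, while the submitters' processing notes name Agilent Feature Extraction 10.7.3.1 for all. Per the file headers, the deposited intensity values are background-subtracted and dye-normalised by a linear factor, and the same files hold Agilent's log10 ratio of Cy5 over Cy3. The deposited series tables hold log2 ratios of Cy5 over Cy3. Set against the scanner files, the table values of acute 28 and acute 25 differed from the scanner values by a constant, and the other 27 columns also carried a smooth correction along the genome. Whether that correction was made for GC content or for another trend was not given in the sources used here. Positions are on the mouse build mm9, per the file headers.

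The log2 ratio of Cy5 over Cy3 was taken from the processed signals, spots flagged as outliers were left out, and spots of 1 probe were averaged. Each array was centred on the median of its autosomal probes outside chromosome 13, with no loess or quantile step. Between 99.84% and 99.96% of spots per array were well above background in both channels. The median background-subtracted Cy3 signal was 75.3 to 168 times the standard deviation of negative controls and the Cy5 signal 85.1 to 221 times. The noise of single probes, from differences between neighbours, was 0.10 to 0.16 on the log2 scale. The number of arrays limits the precision of the comparisons.

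The labels put the tumour in Cy3 and the ear in Cy5. The written plan took the direction of the ratio from these dyes, under which a ratio below 0 is a gain in the tumour. The changes between arrays on chromosome 13 lay in the Cy5 signal, as the closing section describes, so the direction is not settled by the labels. All values are therefore given as Cy5 over Cy3, with "low" for Cy5 below Cy3 and "high" for Cy5 above Cy3. Tests between groups do not depend on this choice.

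Chromosomes were divided into segments by penalised least squares with optimal partitioning (penalty 3 times the variance times the natural log of the number of probes, at least 5 probes). Segments with a mean at or beyond 0.25 either way were called. The run at Ptch1 joined low segments across gaps of up to 0.5 Mb. A whole-chromosome change needed 80% of probes in called segments of 1 direction. Tests were Fisher's exact test for counts and exact permutation tests of the difference of means over all regroupings, where the two-sided p doubles the smaller tail, as scipy does. The tests were first computed with another definition, the share of regroupings with an absolute difference as large. For whole-chromosome changes the 2 definitions fell on different sides of 0.05 (p = 0.0582 and 0.037, both exact), and the choice of the scipy definition was made after both values had been seen. Probe values were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) on the 24 arrays of the larger set, which were 16 acute and 8 protracted. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and numba 0.67.0.

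Arrays were simulated with independent normal values at the median probe noise of the real arrays, 0.123. On them 100.0% of low segments of 5 probes at -0.9 were called, 22.1% of high segments of 5 probes at 0.4 and 96.8% of those of 10 probes. There were 0 false segments on 5 arrays of 52499 probes. For the acute minus protracted fit over 52406 simulated probes, limma recovered 72.0% of probes that differed by 0.25, 94.0% at 0.5, 98.0% at 1 and 100.0% at 2, with 7 false calls. In both simulations the probes were independent of each other, which real neighbouring probes are not. The simulated arrays also carried no trend along the genome and no fixed shifts of single probes. The count of 0 false segments therefore need not hold for the real arrays. In the limma simulation the changed probes were drawn at random over the genome. The shares recovered need not hold on chromosomes where tumours vary more.

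The plan named genes by a column of the files. The scanner files pair no probe with a gene, and the gene table used here is of another build, GRCm38.p6, from which no position was taken. The probe-level fits therefore stand in place of gene-level fits, the 8 gene lists fixed beforehand were not tested, and no gene is named except Ptch1 and its neighbours in gene order. The rule for named genes was Ptch1 always, list members in called changes of 2 or more tumours or past limma, genes at the ends of the common interval, the 5 highest and 5 lowest per fit, and the first and last gene of recurrent segments under 5 Mb. The place of Ptch1 on mm9 was background knowledge, with a margin on both sides.

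Alternatives fixed before the data were examined covered call thresholds of 0.15 and 0.4, penalties of 2 and 6, at least 10 probes per segment, centring on all probes, normexp background correction with an offset of 50, the deposited log2 tables, a filter on dim probes, whole-chromosome changes called from the chromosome median, 1 array design, slide, sex, tumour number and leaving out each tumour. Normexp ran on median signals, since no mean signals were used here. For limma they also covered segment means, loess and permutation tests.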

Results

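DNA copy number was profiled in 29 medulloblastomas, cerebellar tumours that arise in mice with 1 mutated copy of Ptch1. Ptch1 encodes Patched 1, the receptor that holds Hedgehog signalling in check. The acute group held 19 tumours (9 from males, 10 from females), the protracted group 9 (3 from males, 6 from females) and the spontaneous group 1 from a female. The design asks whether tumours after the same 500 mGy, given at once or over postnatal days 1 to 4, carry the same copy number changes, with the region of Ptch1 first. Ratios are log2 of Cy5 over Cy3 for a tumour and the ear of the same mouse. By the dyes in the labels a low ratio would be a gain in the tumour. A tumour in Cy5, for which low is a loss, is the likely direction, because the differences between arrays on chromosome 13 lay in the Cy5 signal, with a median slope on the log2 ratio of 0.955, and not in the Cy3 signal, with -0.0455.

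Chromosome 13 carried a low run over Ptch1 in all 29 tumours. The mean log2 ratio of the probes at Ptch1 was -1.0 ± 0.14 (SD, n = 19) in acute tumours and -1.0 ± 0.10 (SD, n = 9) in protracted tumours, and -0.91 in the spontaneous tumour. A low call at Ptch1 was made in 19 of 19 acute and 9 of 9 protracted tumours (Fisher's exact test, two-sided, p = 1). The depth at Ptch1 differed by 0.0013 between groups (exact permutation test, two-sided, p = 0.973). The call in acute 35 rested on few probes: those at 63570995 and 63610089 read -0.81 and -1.05, and those at 63509581 and 63661725 read 0.08 and -0.11. Its depth at Ptch1, -0.58, averaged the probes at 63610089 and 63661725, and the latter was near 0. On the larger design the depth at Ptch1 rests on these probes. Acute 35 lost its call with a penalty of 6, with at least 10 probes per segment and in the authors' deposited table, which left 27 of 28 tumours called.

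The interval low in all 29 tumours spanned mm9 chromosome 13 from 63570995 to 63661784, a length of 90.8 kb. Its start was set by acute 34 and protracted 26 and its end by acute 35, whose last probe in the interval read -0.11. Without acute 35 it extended to 64605681, a length of 1035 kb, with the end set by protracted 24. In gene order, the protein-coding neighbours of Ptch1 are Fancc, a member of the Fanconi anaemia DNA repair pathway, and Ercc6l2, a helicase-like gene.

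The run ended inside chromosome 13 in 28 of 29 tumours. The exception, acute 19, began at the first probe of the chromosome and ended at 67.0 Mb, and it was left out of the comparison of lengths. Run lengths reached from 0.208 Mb in acute 35 to 64.3 Mb in acute 21 among acute tumours, and from 1.67 Mb in protracted 26 to 64.2 Mb in protracted 19. The spontaneous tumour had a run of 79.7 Mb, from 6.43 to 86.2 Mb. The median was 34.8 Mb in 18 acute tumours and 10.1 Mb in 9 protracted tumours. The mean log10 length in Mb was 1.30 ± 0.64 (SD, n = 18) in acute and 1.02 ± 0.59 (SD, n = 9) in protracted tumours, a ratio of 1.91 between geometric means. The difference of 0.28 did not pass the threshold (exact permutation test, two-sided, p = 0.290, adjusted p = 0.581 over 6 comparisons). Without acute 35, whose run rested on few probes, it was 0.40 (exact permutation p = 0.0645). Runs under 5 Mb occurred in 3 acute and 3 protracted tumours. Within slides the difference was 0.67 on slide 2 (5 acute, 3 protracted, exact permutation p = 0.107), -0.48 on slide 4 (4 and 4, exact p = 0.429), 1.02 on slide 3 and -0.09 on slide 1, where single protracted tumours allow no p under 0.05.

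**Figure D1:**
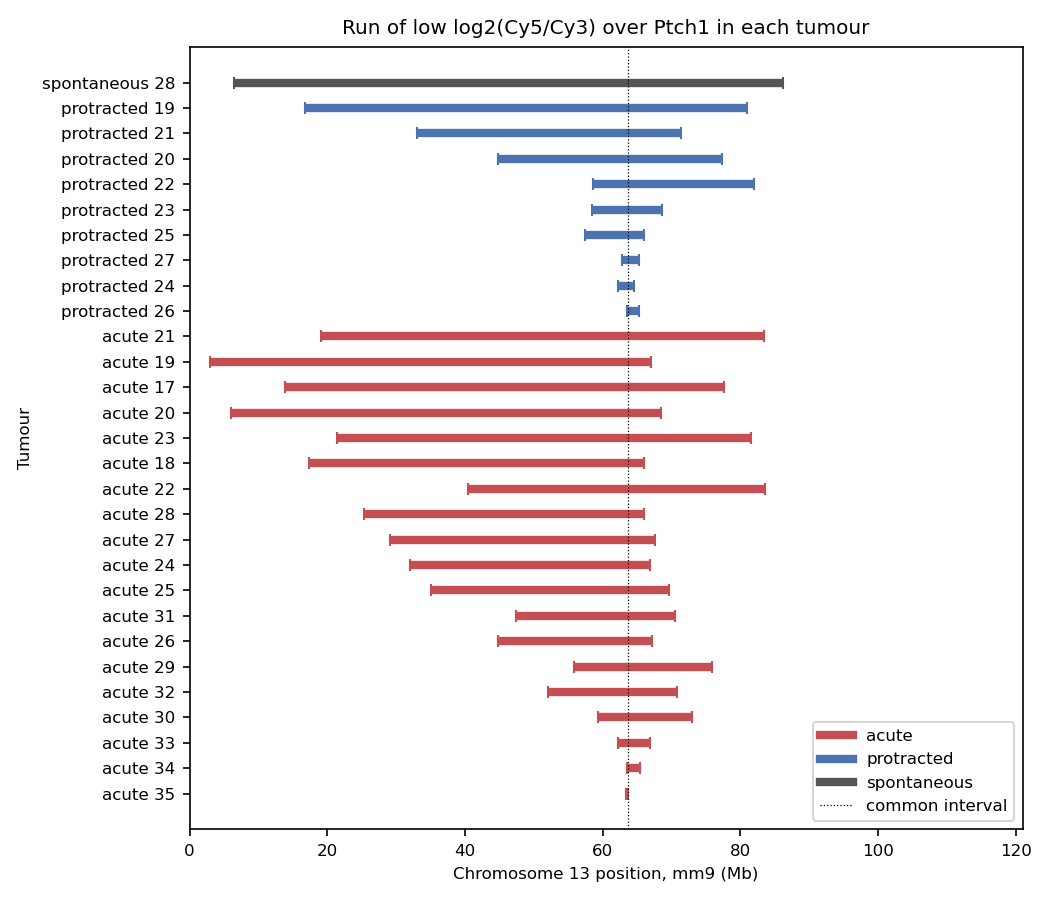
Horizontal bars show the low run over Ptch1 in each of the 29 tumours along chromosome 13 (x axis, mm9 position in Mb), coloured by group, with the common interval dotted. Runs range from 0.208 Mb in acute 35 to 79.7 Mb in spontaneous 28, and all cross the dotted line.

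Chromosome 6 was high as a whole in 16 of 19 acute tumours, in 9 of 9 protracted tumours and in the spontaneous tumour. Its median log2 ratio was 0.40 ± 0.11 (SD, n = 19) in acute and 0.49 ± 0.12 (SD, n = 9) in protracted tumours. The 3 acute tumours without the call were acute 21, acute 23 and acute 33, with medians of 0.12, 0.13 and 0.25. The count depends on the call threshold: at 0.4 in place of 0.25 it was 3 of 19 acute, 4 of 9 protracted and 0 of 1 spontaneous tumours. The highest median was 0.79 in protracted 26. No difference between groups in the frequency of the chromosome 6 change passed the test (Fisher's exact test, two-sided, p = 0.530, adjusted p = 0.707 over 4 chromosome and direction pairs).

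On the other autosomes the whole-chromosome changes called were all high and few. Chromosome 14 was high in acute 34 (0.30) and protracted 23 (0.39). Chromosome 17 was high in protracted 26 (0.38), protracted 27 (0.49) and the spontaneous tumour (0.27), and in 0 of 19 acute tumours (Fisher's exact p = 0.095, adjusted p = 0.381). Chromosome 19 was high in protracted 26 (0.39). With chromosome 6 counted as well, acute tumours carried 0.89 ± 0.46 whole-chromosome changes (SD, n = 19) and protracted tumours 1.44 ± 0.73 (SD, n = 9). The difference of -0.55 did not pass the threshold (exact permutation test, two-sided, p = 0.0582, adjusted p = 0.175 over 6 comparisons). Counting regroupings with an absolute difference as large gave p = 0.037 (exact), and the choice between these definitions was made after both values were seen. Without adjustment, the difference passed when permuted within sexes (-0.60, exact p = 0.0284) and with segmentation penalties of 2 and 6 (-0.60, exact p = 0.0216). It did not pass when permuted within slides (-0.52, exact p = 0.103). Without protracted 26 it was -0.36, within slide 2 it was -1.2 (exact p = 0.179) and within slide 4 it was 0.25 (exact p = 1). With a call threshold of 0.4 the means were 0.16 and 0.56. With a chromosome median at or beyond 0.2 either way as the rule, the difference was -0.29 (exact permutation p = 0.355). Through the run at Ptch1, that rule also counted chromosome 13 as low in acute 17, 18, 19, 20, 21 and 23 and in protracted 19. Its smaller difference thus mixes run length with whole-chromosome changes.

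Called segments covered 6.92% ± 1.93 of the autosomal genome in acute tumours (SD, n = 19), 8.56% ± 2.21 in protracted tumours (SD, n = 9) and 12.7% in the spontaneous tumour. This share includes the run at Ptch1, so run length enters it. Outside chromosome 13 the share in the spontaneous tumour was 9.89%, and the groups were not compared there. With the run included, the difference of -1.65 percentage points did not pass the threshold (exact permutation test, two-sided, p = 0.0528, adjusted p = 0.175). Permuted within sexes it was -1.84 and passed without adjustment (exact permutation p = 0.0236). On slide 2 it was -3.81 (exact p = 0.107), on slide 4 it was 0.73 (exact p = 0.657), and permuted within slides it was -1.68 (exact p = 0.0574). Apart from the run at Ptch1 and whole-chromosome changes, acute tumours had 2.37 ± 2.87 called segments (SD, n = 19) and protracted tumours 3 ± 2.55 (SD, n = 9). The difference was -0.63 (exact permutation test, two-sided, p = 0.619). Where chromosome 6 missed the whole-chromosome call, its called pieces entered this count. With a chromosome median at or beyond 0.2 as the rule, acute 33 had 3 segments in place of 10. The means under that rule were 2 in acute and 3 in protracted tumours. At a call threshold of 0.4, chromosome 6 was called whole in only 3 acute and 4 protracted tumours. The counts at 0.4 can therefore hold pieces of chromosome 6, and their share was not tested. The level depends on the settings: the means were 14.9 and 15.6 with a call threshold of 0.15, 7.16 and 7.33 with 0.4, 7.42 and 7.33 with a penalty of 2, 0.84 and 0.89 with a penalty of 6, 1.32 and 1.67 with at least 10 probes, and 1.58 and 1.56 with normexp. Without protracted 22, which had 9 such segments, the difference was 0.12. Within slide 2 the difference was 0.20 and within slide 4 it was -1.5.

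Probe by probe, 0 of 52406 probes differed between 16 acute and 8 protracted tumours at an adjusted p under 0.05 in limma, and 4367 did at an unadjusted p under 0.05. An exact permutation test per probe also called 0. On X the median limma difference, acute minus protracted, was 0.23, and 0 of 1903 probes passed. The count of 0 thus does not exclude a difference of this size on X. Within slide 2 limma called 34, of which 33 lay on chromosome 13 and all were lower in acute tumours, and within slide 4 it called 0.

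Against a ratio of 0, limma called 38073 probes in acute tumours (17536 high, 20537 low) and 32051 in protracted tumours (15500 high, 16551 low). Most were small shifts of single probes on chromosomes with no whole-chromosome call. On 14 such chromosomes 73.5% of 38098 probes passed in acute tumours, with a median size of 0.11, and 61.4% in protracted tumours, with a median size of 0.13. The 2 groups' probe means correlated at 0.95 across these probes, which are not independent replicates. No array had its dyes swapped by the labels, so dye effects of single probes were not separated from copy number in these counts. With a mean at or beyond 0.25 as well, a limit added after the data were seen, 6599 probes remained in acute tumours and 7437 in protracted tumours. Of these, 2832 of the high ones in acute tumours and 3218 in protracted tumours lay on chromosome 6, and 812 and 300 of the low ones lay on chromosome 13. On X, 801 and 1795 were low. The lowest probe in both groups, A_67_P02707202 at chromosome 13 position 62037154, averaged -3.63 in acute and -2.68 in protracted tumours. It was below 0 in 16 of 16 and 8 of 8 tumours. The highest probe in protracted tumours, A_67_P14490799 at chromosome 6 position 134866619, averaged 1.05 there and 0.95 in acute tumours, and was above 0 in 8 of 8 and 16 of 16.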

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

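The tests on the X chromosome, the bounds they were read against and the test of exposure among them, were chosen after its values were seen. For normally distributed values, chance puts about 1 in 20 groups past the limit used for a single tumour standing apart. That rate need not hold for small counts such as segments and whole-chromosome changes. In the protracted group 6 measures were tested.

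Protracted 22 had 9 altered segments against 5 in the next tumour, which set it apart from the other 8. Protracted 26 had 3 whole-chromosome changes against 2 in the next. With counts from 1 to 3, any lone tumour at 3 passes this limit. Protracted 19, on the smaller array design, had a probe noise of 0.162 against 0.129 in the next. In 5 measures tested, no dependence of the exposure difference on sex passed the threshold, with exact permutation p from 0.252 to 0.704.

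The sex chromosomes lay outside the segment comparisons. X had a median at or below -0.25 in 10 of 17 females and in none of 12 males, whose medians ran from -0.13 to -0.08. The Y median in protracted 26, a male, was -2.21, while the next lowest of 12 males was -0.19.

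The X medians of females were graded, from -1.02 in protracted 24 to -0.09 in acute 32. Ear DNA from a male would move Y as well, but among females with X low the Y median farthest from 0 was -0.30, which argues against it. Normal cells mixed into the tumour would make X and the run at Ptch1 shallow together, but the lowest ratio of X to run depth was 0.315, in protracted 22, which argues against it as the whole account. An exposure effect stays open: the mean was -0.37 ± 0.29 in 10 acute females and -0.58 ± 0.44 in 6 protracted females (exact permutation test, two-sided, p = 0.255; permuted within slides, exact p = 0.45). A change of X in part of the tumour cells may fit the graded values and was not tested.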

How the results depend on the processing

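The definition of the two-sided p, the size limit on probes, the autosomes-only fit, both changes to the joining of segments and leaving out acute 28 with acute 25 were chosen after the data were seen. For the measures per tumour, passing here means an unadjusted p under 0.05. Apart from leaving out single tumours, the share altered passed in 4 of 18 settings. Whole-chromosome changes passed in 4 of 19. The low call at Ptch1 was made in 28 acute and protracted tumours, or 27 where acute 35 lost it. With the sign turned, 0 tumours were low. The length difference turned sign within slide 1 (-0.0872) and slide 4 (-0.48), and ran from 0.18 to 0.40 without each tumour. It passed the threshold with the tumour number as a replicate block (0.71, exact sign-flip p = 0.00781). The numbers do not pair the tumours: 7 same-numbered pairs on the larger design correlated from -0.19 to 0.51, and only protracted 21 correlated best with its own number. The Ptch1 log2 difference turned sign with that block (-0.0342), normexp (-0.0214), the authors' deposited table (-0.00026) and within slide 1 (-0.20) and slide 3 (-0.0657), and ran from -0.0224 to 0.0224 without each tumour. Altered segments turned sign with a penalty of 2 (0.088), normexp (0.023) and within slide 2 (0.20) and slide 3 (0.14), and ran from -1.06 to 0.12 without each tumour. The share altered passed the threshold with penalties of 2 (-1.67, p = 0.0474) and 6 (-1.66, p = 0.0492), normexp (-1.62, p = 0.0499) and within sexes (-1.84, p = 0.0236). It was farther from it with call thresholds of 0.15 (-1.49, p = 0.235) and 0.4 (-1.20, p = 0.206), the authors' table (-1.49, p = 0.0834) and the block (-1.91, p = 0.160), and turned sign within slide 4 (0.73). It ran from -1.95 to -1.19 without each tumour, passing without acute 17, 19, 20 or 34 or protracted 20, 22, 24 or 25. Whole-chromosome changes passed with penalties of 2 and 6 (-0.60, p = 0.0216), within sexes (-0.60, p = 0.0284) and by absolute differences (-0.55, p = 0.037). They were farther from it with call thresholds of 0.15 (-0.50, p = 0.0767) and 0.4 (-0.40, p = 0.157), the chromosome median (-0.29, p = 0.355), normexp (-0.49, p = 0.107), the authors' table (-0.50, p = 0.0767), within slides (-0.52, p = 0.103) and the block (-0.67, p = 0.125), and turned sign within slide 4 (0.25). They ran from -0.61 to -0.36 without each tumour, passing without acute 34 or protracted 19, 20, 21, 22, 24 or 25. Probes differing between groups numbered 0 in every limma setting run and without each tumour, except 34 within slide 2. Within slide 2, 21260 probes in acute and 16017 in protracted tumours differed from 0, where fewer arrays were tested, and 6599 and 7437 passed with the size limit. Without each tumour these counts ran from 37155 to 38548 and from 30211 to 32638. The causes of the other changes were not tested. Cy3 signals were at least 75.3 times the spread of negative controls; what this limits was not tested. Gene lists were not run.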

Other observations

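The tests of explanations in this part, with the bounds they were read against, and the look at other splits were chosen after the values were seen, while the limma fit was planned.

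Overlapping low segments on chromosome 4 in acute 29, protracted 23 and the spontaneous tumour together spanned 2.25 Mb, from 111696154 to 113944617. Their means ran from -0.60 to -0.29. The span joins separate calls, so each tumour need not be low over all of it. On chromosome 14, overlapping calls joined in the same way spanned 73724433 to 73730463. They came from 9 tumours, low in 5 and high in 4. Acute 21, acute 26 and protracted 22, all on slide 2, had overlapping high segments under 5 Mb. These joined spans began at 11585159 on chromosome 11 and at 44674939 on chromosome 4.

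The low run at Ptch1 was tested for its direction. Were the tumour in Cy3 with extra copies, the Cy3 signal would carry the differences between arrays. The slope of the Cy5 signal on the log2 ratio was taken over 810 variable probes of chromosome 13 on 24 arrays. Its median was 0.955 (quartiles 0.918 and 0.991). The Cy5 signal thus carried the differences, which argues against extra copies in a tumour labelled with Cy3. Outside the common interval, 38.1% of 8114 values were above -0.25 at probes low in 10 or more other arrays. These values repeat the same probes on 24 arrays, and the share ran from 0% in acute 23 to 94.8% in acute 35. They cannot decide on probes that read low on every array, since the interval was defined as the stretch low in all tumours. Inside the interval, a probe effect added to copy number is argued against by a median difference of -0.0617 from the run around it (quartiles -0.129 and -0.00713, 23 arrays). A reading there unrelated to copy number was not tested. A dye assignment opposite to the labels, with low as a loss in the tumour, is the likely reading.

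Inside the run, 7 probes from 61780891 to 62158800 fell far below the rest of it, to a median of -2.74 in 18 tumours whose run covered them. Probe behaviour unrelated to the run is argued against, since 6 tumours whose run did not reach these probes had a median of -0.127. A candidate explanation is an inherited copy difference between the parental homologues, with the same homologue low in each tumour. It stays open: 5 of 5 tumours of the smaller design fell at least 0.5 below their run there. The test assumed an even chance of either homologue (exact binomial p = 0.0625). With 5 tumours it could not give a p under 0.05, so it decides nothing about this explanation. The 18 tumours that prompted the test are not counted. A deeper change arising separately in each tumour was not tested, and the parental strains were not analysed here.

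In limma, 0 probes differed between acute and protracted tumours. The count of splits decides nothing, since all 100 splits of the 24 tumours, the real one included, give 0 or more. Of 99 other splits, 98 called 0 and the highest called 1609, of which 1588 lay on X. That split had 7 females among 8 tumours in 1 part and 6 among 16 in the other. It points to a structure of the tumours on X, whose cause was not tested.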
